A study of Homo sapiens with 6 samples.

How the data were processed

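Poly(A) RNA of QBC-939 cells was sequenced as paired-end libraries on an Illumina NovaSeq, with 3 libraries from cells given a scrambled shRNA (control) and 3 from cells given an shRNA against BMI1, each 48 h after treatment, per the labels. The labels name the reagents as shRNA in the treatment protocol and also as siRNA for the control in the design text; shRNA is used here. The extraction protocol also names adipose material, which none of these samples is, so whether its library details (poly(A) selection, read layout and instrument) hold for these samples is not settled. One table held all 6 libraries. Its columns carry the abbreviations Sc and Sh with a number; they were taken as scrambled and Bmi1 shRNA with the replicate number of the sample titles, and no column was left unused.

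The values are FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library), as deposited by the authors. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used, with no role given for each, and the genome build is named mm8, a mouse build. The organism in the labels is human and 19870 of the 27238 row names are symbols of a human gene table, so the build that was used is not settled. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The table gives no coordinates and no read counts. 3646 rows share 1355 repeated names, 25 names were turned into dates, and no row stood at 0 in all libraries. Rows with a repeated name were tested but are not named. The depth of the libraries is unknown: low values were compared between libraries in search of the steps of whole reads, and at most 7.10% of low rows shared the commonest ratio to control replicate 1, so reads could not be recovered and no count test was run. FPKM are relative to the fragments of each library, so a change in total mRNA per cell cannot be seen from them. Their sum is not fixed, and it was higher in all 3 Bmi1 shRNA libraries (352800 to 360371) than in the control libraries (332910 to 341268).

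Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, over the 11016 rows with a mean of at least 1 FPKM across the 6 libraries, with group as the sole term and eBayes with a trend in the variance. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and also counted at an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale unless given as ratios of mean FPKM, and understate the change of low genes. BMI1 was also tested by an exact two-sided permutation of FPKM. Before the data were examined, 42 gene lists were fixed; the 38 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those lists, and beside it with camera at an estimated correlation and with fry.

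The genes named in the text were set by a rule, also fixed then: BMI1; the 12 largest rises and the 12 largest falls by log2 fold change among called genes with a gene symbol and no overlap between the groups; up to 4 members with the smallest p in each list described; and members of the PRC1 and CDK inhibitor lists. BMI1 counts under 3 parts of the rule. Some genes that the rule would name are not reported here, though they stay in the counts. Genes named outside the rule are said to have been chosen after their values were seen.

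GC content and length were taken from GENCODE 29 transcripts (GRCh38), used also for the position of BMI1, and were known for 92.8% of tested rows. To remove the trend, the deviation of each library from the gene's mean was regressed on natural splines of GC content and of log2 length (5 degrees of freedom each) and the fitted part subtracted; this was chosen after seeing the data. It removes any true change that goes with GC content or length as well. GC content was first taken as the median over a gene's transcripts and, after a first run had been seen, as that of the longest protein-coding transcript, because short fragments of the annotation set the median of some genes; both versions are given. Lists were compared with 10000 random lists matched on GC content, length and expression; after the first run, a list's own members were left out of the pool from which its random lists were drawn.

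Alternatives covered the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), scaling (each library to a total of 1000000, to one upper quartile, or quantile normalization), the variance prior, library weights, the replicate number as a block, a test against a fold of 1.5 (limma's treat) and each library left out in turn. The count tests listed beforehand for the case of raw counts were not run.

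The steps were tested on simulated data built on the 11016 tested rows with the spread of these libraries, with 200 genes changed. Of genes changed by 0.5 on the log2 scale 62% were called, and of those changed by 1, 89%; 10 of the 161 calls were unchanged genes. With a GC trend added to one group, 4703 unchanged genes were called among 10226, and 10 once the trend had been removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.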

Results

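The mRNA of QBC-939 cells, which the labels give as a human cholangiocarcinoma (cancer of the bile duct) line, was measured 48 h after delivery of an shRNA against BMI1 or of a scrambled shRNA. BMI1 is a RING finger protein of Polycomb repressive complex 1 (PRC1), which places ubiquitin on histone H2A and holds developmental genes and the CDKN2A locus in a silent state. Each group held 3 libraries, described as independent transfections, and the values were FPKM for 27238 named rows. The FPKM values of a library summed to between 332910 and 360371. The number of reads per library is not given in the sources used here, so no counting interval could be attached to any value. Across genes, log2(FPKM + 1) correlated between libraries of one group with r from 0.983 to 0.986 and between groups with r from 0.948 to 0.960. These are correlations across genes, which are not independent replicates. The first principal component, which separated the groups, held 62.8% of the variance. The comparison asked how the mRNA profile of these cells differs when BMI1 is lowered.

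BMI1 itself was lower in every library treated with its shRNA. It measured 6.65, 5.34 and 6.09 FPKM in the control libraries and 1.49, 1.19 and 2.65 FPKM in the Bmi1 shRNA libraries, so that 6.02 ± 0.659 FPKM (SD, n = 3) fell to 1.78 ± 0.770 FPKM (SD, n = 3), 29.5% of control. The log2 fold change was -1.37 with a standard error of 0.19 (limma, adjusted p = 0.00162). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. The gene (ENSG00000168283.13) lies on the forward strand of chromosome 10 from 22321211 to 22331484 in GRCh38. Its span overlaps that of the annotated readthrough gene COMMD3-BMI1 (22316388 to 22329542), which has no row in the table, so reads from that transcript cannot be told from those of BMI1 here. The neighbouring gene COMMD3, chosen after its values were seen, rose from 11.8 ± 0.506 to 16.7 ± 1.16 FPKM (SD, n = 3 each; limma, adjusted p = 0.00192). Its log2 fold change of 0.47 was 0.39 once the trend with GC content and length had been removed, but 0.065 and not called with GC content and length taken as medians over transcripts (limma, adjusted p = 0.397).

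Among the genes with the largest rises were several that encode secreted proteins or regulators of secretory cells. TFF3, a trefoil peptide secreted with mucus, rose from 9.95 ± 0.382 to 64.7 ± 6.37 FPKM (SD, n = 3 each; 6.51-fold), and SPINK4, a protease inhibitor of goblet cells, from 0.586 ± 0.244 to 8.52 ± 0.801 FPKM. NEUROG3, the transcription factor of endocrine progenitors, rose from 0.718 ± 0.162 to 6.17 ± 0.317 FPKM. MDK, the growth factor midkine, rose 4.49-fold, from 5.58 ± 0.270 to 25.1 ± 1.63 FPKM. The largest falls included CLDN2, a pore-forming tight junction protein, from 386 ± 6.80 to 165 ± 6.44 FPKM, and BMP4, a secreted ligand of the BMP pathway, from 70.8 ± 10.6 to 30.8 ± 1.32 FPKM.

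**Figure D1:**
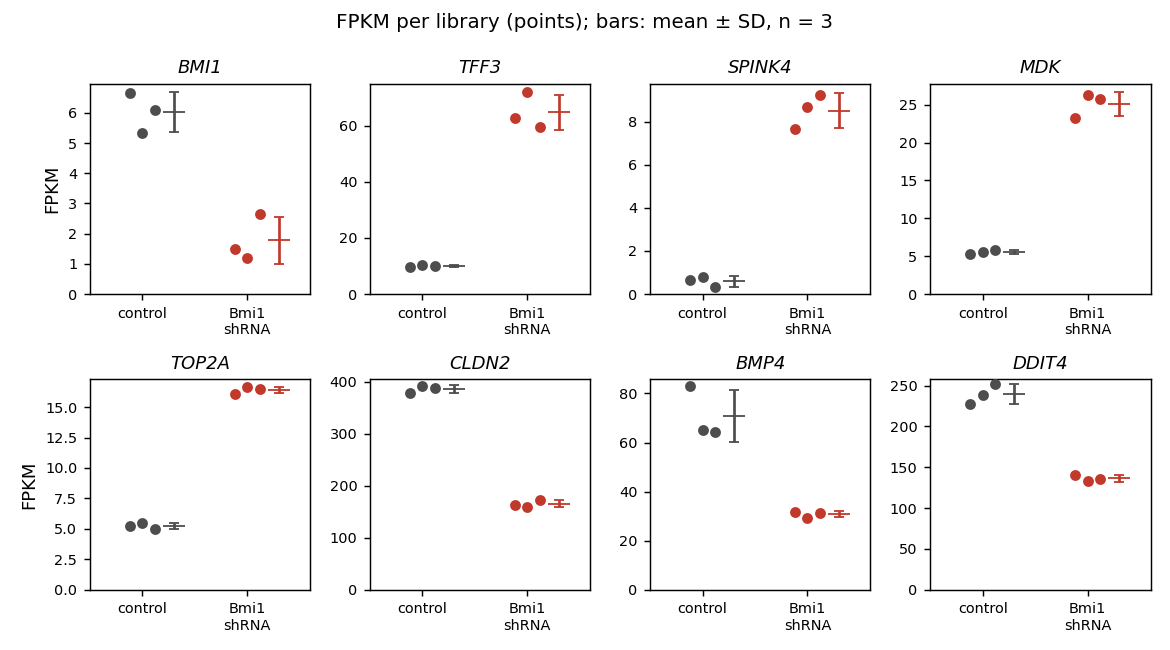
FPKM (vertical axes, starting at 0) of 8 genes in the 3 control and 3 Bmi1 shRNA libraries; points are libraries, and the bars beside them give the mean and SD of the group. BMI1, CLDN2, BMP4 and DDIT4 are lower and TFF3, SPINK4, MDK and TOP2A higher in all 3 Bmi1 shRNA libraries, with no overlap between the groups.

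The other genes among the 12 largest rises covered metabolism, matrix and transport. SUCNR1, the succinate receptor, rose from 1.36 ± 0.180 to 12.7 ± 0.658 FPKM, and TFRC, the transferrin receptor, from 11.5 ± 0.608 to 40.0 ± 1.91 FPKM. MMP1, the interstitial collagenase, rose 4.67-fold, FXYD2, a regulatory subunit of the sodium pump, 3.46-fold, and NEURL1, a ubiquitin ligase, 5.99-fold. ARPIN-AP3S2, a readthrough gene, rose from 0.739 ± 0.147 to 12.5 ± 1.78 FPKM. The genes it joins, looked at after its value was seen, fell: ARPIN had a log2 fold change of -0.56 and AP3S2 of -1.14. Reads of these overlapping genes may have been assigned to one or the other, so the change is uncertain for all 3. RN7SL5P (log2 fold change 2.29) and RNU1-2 (1.90) belong to families of near-identical copies and are uncertain for the same kind of reason.

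The 12 largest falls held genes of adhesion, ion transport and the mitochondrial ribosome besides BMI1, CLDN2 and BMP4. TNS4, a focal adhesion protein, fell from 83.3 ± 6.78 to 35.3 ± 4.68 FPKM. The mitochondrial ribosomal protein genes MRPS2 and MRPL49 fell by 1.17 and 1.18 on the log2 scale. PRR5L, which binds mTORC2, fell by 1.26, LRRC8E, a subunit of volume-regulated anion channels, fell by 1.18, and ZNF672, a zinc finger gene, fell by 1.48. The small nucleolar RNAs SNORD26 and SNORD83A fell by 1.84 and 1.19; RNAs this short are poorly captured by poly(A) selection. Over all 24 genes, limma's adjusted p ran from 7.9e-05, for TFF3 and others, to 0.0228 for RN7SL5P, and each was higher, or lower, in 3 of 3 Bmi1 shRNA libraries. Leaving out 1 library ended the call of RN7SL5P (without control replicate 2 or 3 or Bmi1 shRNA replicate 2; adjusted p up to 0.0652), ZNF672 (without control replicate 2 or 3 or Bmi1 shRNA replicate 1 or 3; up to 0.0582) and LRRC8E (without control replicate 2 or 3 or Bmi1 shRNA replicate 2; up to 0.0634). ZNF672 and LRRC8E were also not called once the trend with GC content had been removed (adjusted p = 0.0585 and 0.0613). Their log2 fold changes were then -1.21 and -0.87, and with medians over transcripts all 24 genes were called. With no filter on low values RN7SL5P, ZNF672 and LRRC8E were not called (adjusted p = 0.0676, 0.0581 and 0.0598).

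In all, 6295 of 11016 tested genes passed the threshold (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05), 3152 higher and 3143 lower with Bmi1 shRNA. Of these, 212 were at least 2-fold higher and 48 at least 2-fold lower on that scale, which understates the change of low genes. At an unadjusted p under 0.05 there were 6896 genes. The groups did not overlap for 7200 genes, 65.4% of those tested, where chance gives 10%. The median log2 fold change over tested genes was -0.02.

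The direction of a gene's change went with the GC content of its transcript. Tested genes were put in order of GC content and parted into 10 equal groups. In the group with the lowest GC content (up to 39.5%) the median log2 fold change was 0.49, with 74.7% of genes higher and 1.37% lower. In the group with the highest GC content the median was -0.15, with 14.5% of genes higher and 35.9% lower. The lowest median, -0.24, stood in the 8th group. Spearman's rho of the log2 fold change with GC content was -0.474 over 10226 genes with a known transcript and -0.343 over 686 lncRNA and pseudogene rows; both are across genes. Shorter transcripts were also higher, from a median of 0.34 in the shortest of 10 groups by length to -0.17 in the longest. With the GC content and length trend removed from each library, a step chosen after seeing the data, 4064 of 10226 genes passed (1952 higher, 2112 lower), of which 54 were at least 2-fold higher and 23 at least 2-fold lower. Of the 5977 genes called before that had a known transcript, 2936 were called in the same direction after it and 125 in the opposite one. A further 1003 were called only after it. BMI1, at 39.1% GC, had a log2 fold change of -1.79 after it (limma, adjusted p = 0.00138). For each gene group, the median GC content of its tested members is therefore given, against 50.4% over all tested genes.

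**Figure D2:**
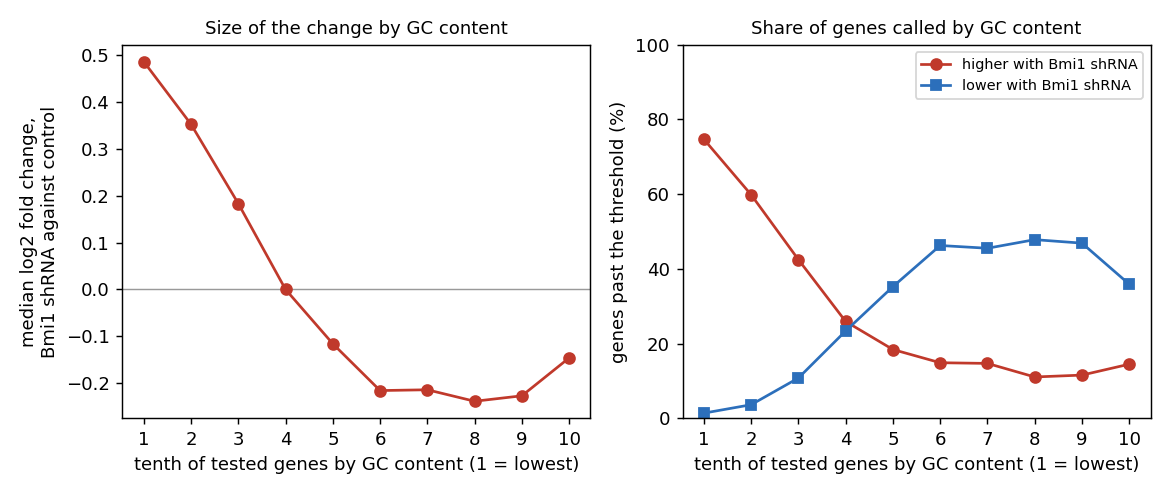
Left, the median log2 fold change of Bmi1 shRNA against control (vertical axis) in 10 equal groups of tested genes ordered by the GC content of the transcript (horizontal axis, 1 lowest); right, the percentage of genes in each group past the threshold, higher (circles) or lower (squares). The median goes from 0.49 in the lowest group to -0.24 in the 8th, and the percentage of genes that were higher from 74.7% in the lowest to 14.5% in the highest.

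Of 38 gene lists with at least 5 tested members, 14 passed camera with its preset correlation, 3 up and 11 down. None passed with an estimated correlation, where the lowest adjusted p was 0.535, while fry, which asks only whether the members of a list move one way on balance, called 27. List medians were also placed among those of random lists matched on GC content, length and expression, a step chosen after seeing the data. Among falling lists, PRC1 (36.16th percentile), developmental factors (17.92), hypoxia (32.99), immediate early (61.87), transporters (21.4) and NOTCH (2.78) lay inside the middle 95%. TGF-beta (2.01), integrated stress response (0.03), WNT (0.01), epithelial (0) and YAP (0) lists lay below it.

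Genes of translation, respiration and mitosis made up the lists that rose. Of 79 genes for cytosolic ribosomal proteins, 60 rose, none fell and 19 did not pass (64 rose adjusted over the list alone). The median log2 fold change was 0.35 (camera adjusted p = 8.86e-10; adjusted p = 0.535 with an estimated correlation). RPL7 rose from 113 ± 3.22 to 261 ± 27.2 FPKM (SD, n = 3 each), RPL37 from 329 ± 13.9 to 541 ± 15.7 FPKM and RPL6 from 88.5 ± 4.29 to 146 ± 1.46 FPKM. Reads of these genes can be shared with their processed pseudogenes. The list had a median GC content of 49.1% and, with the trend removed, held 33 genes higher and 6 lower at a median of 0.18. Of 61 nuclear genes for oxidative phosphorylation, 47 rose, 3 fell and 11 did not pass (48 rose and 3 fell adjusted over the list alone; camera adjusted p = 9.22e-10; adjusted p = 0.535 with an estimated correlation). UQCR11 of complex III rose 1.82-fold, from 77.3 ± 4.73 to 141 ± 0.870 FPKM, and NDUFB2 and NDUFB11 of complex I rose 1.83-fold and 1.52-fold. COX7C, at 39.0% GC, rose 1.65-fold in the deposited values and had a log2 fold change of 0.01 with the trend removed. The list had a median GC content of 47.9%; with the trend removed 29 were higher and 4 lower, and the median went from 0.50 to 0.20.

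Of 50 G2/M genes, 29 rose, 5 fell and 16 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.0001; adjusted p = 0.535 with an estimated correlation). TOP2A, the topoisomerase of mitotic chromosomes, rose from 5.23 ± 0.240 to 16.4 ± 0.274 FPKM (SD, n = 3 each), CDK1 from 6.24 ± 0.742 to 17.6 ± 0.863 FPKM and HMMR, a spindle protein, from 1.95 ± 0.0609 to 5.94 ± 0.135 FPKM. The median GC content was 44.3%. Of its members 25 were higher and 2 lower with the trend removed, and the median went from 0.37 to 0.26. Genes of G1/S, by contrast, went both ways: 14 of 43 rose and 13 fell, also adjusted over the list alone (camera adjusted p = 0.851; median GC content 45.6%), and 10 were higher and 13 lower with the trend removed. Among them MCM6 rose from 3.95 ± 0.276 to 9.61 ± 0.185 FPKM and RRM1, of ribonucleotide reductase, from 7.13 ± 0.580 to 15.4 ± 0.654 FPKM. The difference between these lists was not tested.

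Several components of PRC1 other than BMI1 were lower. Of 24 tested PRC1 genes, 13 fell, 3 rose and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.0487; adjusted p = 0.535 with an estimated correlation). BCOR, of the PRC1.1 form, fell from 3.47 ± 0.156 to 1.82 ± 0.287 FPKM (SD, n = 3 each), SCMH1 from 7.72 ± 0.460 to 5.21 ± 0.459 FPKM and RING1, a catalytic partner of BMI1, from 33.2 ± 0.377 to 26.7 ± 1.80 FPKM. Its paralog RNF2 rose from 3.60 ± 0.204 to 5.14 ± 0.292 FPKM. PCGF2, the closest paralog of BMI1, had a log2 fold change of 0.11 with a standard error of 0.20 (limma, adjusted p = 0.645). PCGF1, PHC2, CBX7, CBX6 and KDM2B also fell, by 1.25-fold to 1.44-fold, as did L3MBTL2, CBX2 and BCORL1, and PCGF6 and SCML1 rose. The list had a median GC content of 54.0%. After removal of the trend 8 were lower, among them BMI1, BCOR, SCMH1, PCGF1 and RING1, and 2 higher (camera adjusted p = 0.33), with RNF2, SCML1, CBX2, CBX6, KDM2B and BCORL1 taking the opposite sign. With medians over transcripts the list was not called either (camera adjusted p = 0.0684), KDM2B kept its sign, and PCGF1 and RING1 were not called (log2 fold change -0.092 and -0.098; limma, adjusted p = 0.278 and 0.144). The call of the list, close to the threshold, also ended with a pseudocount of 0.1 (camera adjusted p = 0.0538), with libraries scaled to a total of 1000000 (0.0527), with quantile normalization (0.0536) and with the replicate block (0.0548). The block ended the calls of SCML1, CBX2 and BCORL1 as well (limma, adjusted p = 0.0639, 0.0798 and 0.0879), and so did the fit with no filter on low values (0.0598, 0.0563 and 0.0840). SCML1 was also not called with libraries scaled to a total of 1000000 (0.0650) or with quantile normalization (0.0835), nor BCORL1 with upper quartile scaling (0.0518). The list's call further ended without control replicate 1 or 3 or Bmi1 shRNA replicate 1 or 2 (adjusted p up to 0.0746), as did those of L3MBTL2 (without control replicate 2), CBX2 (without control replicate 2 or 3 or Bmi1 shRNA replicate 1 or 2), SCML1 (without any control replicate or Bmi1 shRNA replicate 1) and BCORL1 (without any library but control replicate 3), at adjusted p up to 0.111.

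Known and candidate targets of Polycomb moved in both directions. CDKN2A, which encodes the cell cycle inhibitors p16 and ARF, rose from 31.6 ± 1.57 to 42.0 ± 2.22 FPKM (SD, n = 3 each; 1.33-fold; limma, adjusted p = 0.00273). At 61.4% GC, its log2 fold change was 0.40 before and 0.31 after removal of the trend. CDKN1B fell from 16.2 ± 0.174 to 11.6 ± 0.145 FPKM and CDKN2B from 3.19 ± 0.0742 to 2.66 ± 0.197 FPKM. The call of CDKN2B ended without any 1 library other than Bmi1 shRNA replicate 3 (adjusted p up to 0.108). It also ended with the replicate block (0.0938), with upper quartile scaling (0.0531) and with no filter on low values (0.0723). With the trend removed its log2 fold change went from -0.20 to -0.24 and was called (limma, adjusted p = 0.0122). With medians over transcripts its sign turned (log2 fold change 0.088) and it was not called (limma, adjusted p = 0.191). CDKN1A (24.8 ± 0.939 and 21.7 ± 3.05 FPKM), CDKN1C (1.03 ± 0.179 and 1.37 ± 0.407), CDKN2C (6.72 ± 0.632 and 6.62 ± 0.566) and CDKN2D (7.86 ± 0.905 and 7.98 ± 0.877) did not pass. CDKN1C did without Bmi1 shRNA replicate 1 (adjusted p = 0.0314). Over the 7 CDK inhibitors 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.745; median GC content 58.1%). Of 22 HOX genes 3 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.541; median GC content 55.2%), among them HOXA9, down from 5.05 ± 0.299 to 3.35 ± 0.223 FPKM, and HOXB7, up from 30.1 ± 0.275 to 35.7 ± 0.723 FPKM, the latter not called with the trend removed (limma, adjusted p = 0.0544). Removal of the trend turned the balance of the HOX genes to 6 higher and 3 lower, with the median going from -0.07 to 0.03 (camera adjusted p = 0.572).

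Of 14 developmental transcription factors that carry Polycomb marks in other cells, 6 fell, 1 rose and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.535 with an estimated correlation). GATA6 fell from 14.7 ± 0.622 to 8.57 ± 0.421 FPKM (SD, n = 3 each), FOXC1 from 2.65 ± 0.123 to 1.21 ± 0.126 FPKM and ZIC2 from 5.63 ± 0.556 to 3.23 ± 0.365 FPKM. The 1 that rose was ATOH1, the transcription factor of intestinal secretory cells, from 2.26 ± 0.285 to 5.39 ± 0.498 FPKM. The median GC content was 55.8%. With the trend removed 5 were lower and 2 higher, the median going from -0.26 to -0.16 (camera adjusted p = 0.215). Of 12 components of PRC2, 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.731; median GC content 45.5%). MTF2 rose from 0.681 ± 0.102 to 1.55 ± 0.0348 FPKM and EZH2, the methyltransferase, from 8.44 ± 0.570 to 10.3 ± 0.224 FPKM. Neither passed with the trend removed (limma, adjusted p = 0.0944 and 0.0886), nor EZH2 with libraries scaled to a total of 1000000 (0.0584).

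The lists of epithelial genes and of YAP targets were lower. Of 35 epithelial genes, 18 fell, none rose and 17 did not pass, also adjusted over the list alone (camera adjusted p = 0.000989; adjusted p = 0.535 with an estimated correlation). The desmosomal gene PKP3 fell from 33.9 ± 0.396 to 22.9 ± 0.116 FPKM (SD, n = 3 each), CDH3, which encodes P-cadherin, from 9.97 ± 0.530 to 5.84 ± 0.386 FPKM and KRT19 from 287 ± 6.98 to 211 ± 14.2 FPKM. The median GC content was 56.2%. Removal of the trend left 16 lower and 1 higher, the median going from -0.36 to -0.22 (camera adjusted p = 0.00386). Of 13 YAP targets 12 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.535 with an estimated correlation). CCN1, a matricellular protein, fell from 14.7 ± 0.748 to 7.95 ± 0.692 FPKM, CRIM1 from 2.23 ± 0.354 to 0.793 ± 0.0437 FPKM and F3, tissue factor, from 4.83 ± 0.398 to 2.65 ± 0.324 FPKM. Their median GC content was 50.3%. With the trend removed 8 were lower and none higher, with the median going from -0.54 to -0.41 (camera adjusted p = 0.00722). Over genes with a mean FPKM of at least 5 the YAP list was not called (camera adjusted p = 0.204).

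The lists of the integrated stress response, of hypoxia and glycolysis and of immediate early genes fell as well. Of 39 genes of the integrated stress response, which ATF4 drives when translation or amino acids are limited, 24 fell, 7 rose and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.00657; adjusted p = 0.535 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell by 0.81 on the log2 scale with a standard error of 0.06. The amino acid transporter subunit SLC3A2 fell from 115 ± 2.53 to 68.7 ± 2.87 FPKM (SD, n = 3 each) and SESN2 from 22.4 ± 1.03 to 11.3 ± 0.708 FPKM. EPRS, a tRNA synthetase, rose from 10.1 ± 0.266 to 19.9 ± 0.542 FPKM. The median GC content was 52.7%. Removal of the trend left 21 lower and 7 higher, with the median going from -0.35 to -0.30 (camera adjusted p = 0.0145). Of 34 genes of hypoxia and glycolysis, 16 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.535 with an estimated correlation). SLC2A1, a glucose transporter, fell from 347 ± 8.95 to 196 ± 12.9 FPKM, HK2, a hexokinase, from 7.60 ± 0.690 to 3.81 ± 0.193 FPKM and PFKFB3 from 7.68 ± 0.728 to 3.31 ± 0.387 FPKM. Of 24 immediate early genes 10 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.535 with an estimated correlation). JUN fell from 43.7 ± 2.84 to 21.7 ± 0.405 FPKM, and BTG2, an inhibitor of proliferation, was the 1 that rose, from 7.46 ± 0.491 to 13.5 ± 0.974 FPKM. The hypoxia and immediate early lists had a median GC content of 54.9% and 55.6%. Neither was called with the trend removed (camera adjusted p = 0.255 and 0.273). The median of the hypoxia list went from -0.21 to -0.14, with 10 lower and 4 higher. That of the immediate early list went from -0.18 to -0.04, with 8 lower and 2 higher.

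Targets of WNT and TGF-beta signalling, targets and components of NOTCH signalling and genes for ABC transporters made up the remaining lists that fell. Of 15 WNT targets 9 fell and 2 rose (camera adjusted p = 0.026), and of 19 TGF-beta targets 11 fell and 3 rose (camera adjusted p = 0.0385). Of 10 genes in the NOTCH list 7 fell and none rose (camera adjusted p = 0.0385). All had the same counts adjusted over the list alone. With an estimated correlation the adjusted p was 0.535 for each of these lists. The WNT counts leave out LGR5, NKD1, TNFRSF19 and NOTUM, whose mean lay under the filter of 1 FPKM. All of these had a higher mean with Bmi1 shRNA, against the direction of the list. NKD1 went from 0.296 ± 0.0322 to 0.474 ± 0.0322 FPKM and TNFRSF19 from 0.0563 ± 0.0122 to 0.264 ± 0.0524 FPKM. For NOTUM the spread of the groups overlapped (0.0533 ± 0.0652 and 0.132 ± 0.0715 FPKM). The NOTCH list is not one of targets alone: beside HES1 it holds the ligands JAG1 and JAG2 and the coactivator MAML3, which also fell. CCND1, cyclin D1, fell from 20.2 ± 0.425 to 10.9 ± 0.314 FPKM (SD, n = 3 each), TCF7L2 from 4.88 ± 0.481 to 1.90 ± 0.222 FPKM, BHLHE40 from 14.2 ± 0.445 to 8.04 ± 0.704 FPKM and HES1, a NOTCH-induced repressor, from 18.9 ± 0.335 to 12.3 ± 1.03 FPKM. SKIL, an inhibitor of TGF-beta signalling and itself its target, rose from 1.15 ± 0.179 to 3.00 ± 0.233 FPKM. Of 12 ABC and drug transporter genes 7 fell and none rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0255; adjusted p = 0.607 with an estimated correlation), with ABCC3, an exporter of bile salts and conjugates, down from 19.7 ± 0.875 to 10.3 ± 0.605 FPKM. The median GC content was 53.9%, 52.0%, 53.6% and 55.4% in the WNT, TGF-beta, NOTCH and transporter lists. None of them was called with the trend removed (camera adjusted p = 0.0726, 0.124, 0.26 and 0.417). In the same order, the medians went from -0.55 to -0.22, -0.29 to -0.26, -0.41 to -0.10 and -0.36 to -0.11. The WNT list then held 9 lower and 2 higher, the TGF-beta list 8 and 4. The NOTCH list held 5 lower and none higher, and the transporter list 6 and 1. The WNT and NOTCH calls also ended with no filter on low values, and the WNT, TGF-beta and NOTCH calls over genes with a mean FPKM of at least 5 (camera adjusted p = 0.137 and 0.0928; then 0.228, 0.426 and 0.262). The NOTCH call further ended with libraries scaled to a total of 1000000 (camera adjusted p = 0.0527), with quantile normalization (0.0536), with the replicate block (0.0548) and without Bmi1 shRNA replicate 3 (0.0567).

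**Figure D3:**
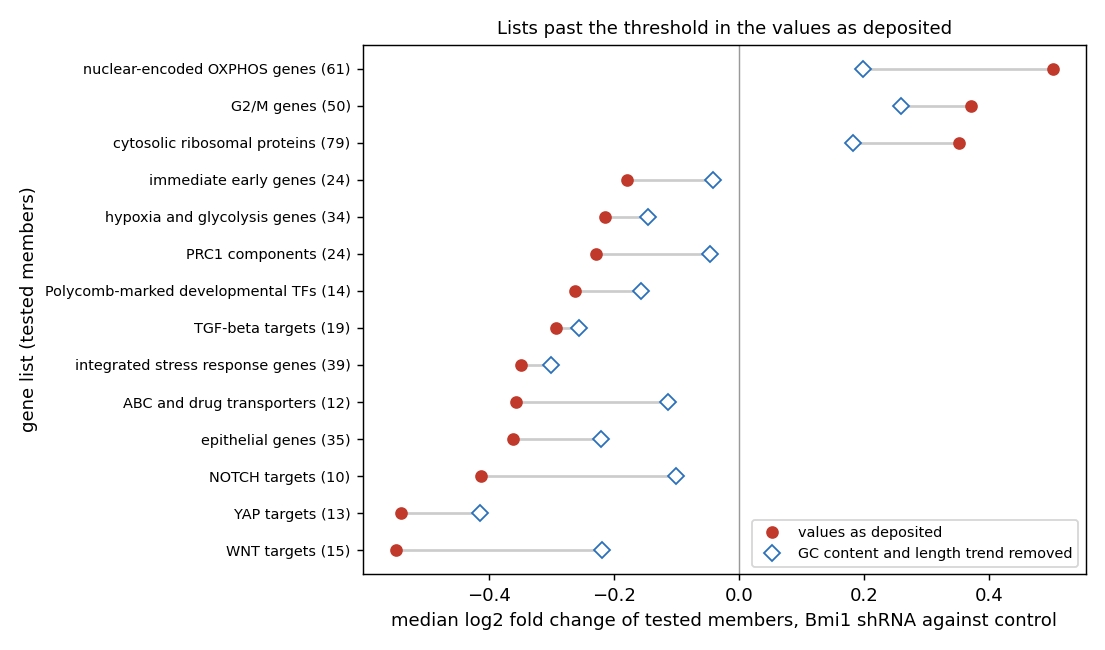
Median log2 fold change of Bmi1 shRNA against control (horizontal axis) over the tested members of the 14 lists past the threshold (vertical axis, number of tested members in parentheses), in the deposited values (circles) and with the GC content and length trend removed (diamonds). Every median keeps its sign and lies nearer to 0 with the trend removed; that of oxidative phosphorylation genes goes from 0.50 to 0.20 and that of integrated stress response genes from -0.35 to -0.30.

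The 13 mitochondrially encoded mRNAs did not move as a list in the deposited values (3 rose and 5 fell, also adjusted over the list alone; camera adjusted p = 0.541). MT-ND1 fell from 3429 ± 75.2 to 2340 ± 29.9 FPKM (SD, n = 3 each) and MT-CO1 by 0.48 on the log2 scale, while MT-ND3 rose from 2013 ± 30.6 to 3649 ± 182 FPKM. Their median GC content was 44.3%. With the trend removed 11 were lower and none higher, the median going from -0.07 to -0.67 (camera adjusted p = 1.76e-05). MT-ND3 then had a log2 fold change of -0.01.

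The other lists were not called, with camera adjusted p from 0.0762 to 0.959, though many of their members changed. Of 25 p53 targets 8 rose and 7 fell (9 and 8 adjusted over the list alone). CCNG1 rose from 6.75 ± 0.181 to 16.9 ± 1.39 FPKM and TNFRSF10B fell from 13.5 ± 0.428 to 8.41 ± 0.475 FPKM (SD, n = 3 each). Of 16 interferon-stimulated genes 6 rose, such as IFI16 from 0.720 ± 0.0852 to 1.94 ± 0.123 FPKM, and 7 fell, such as OASL from 6.22 ± 0.733 to 3.21 ± 0.335 FPKM, also adjusted over the list alone. Members rose and fell as follows in the remaining lists of cell function: 8 and 1 of 23 apoptosis regulators (7 and 1 adjusted over the list alone), 2 and 5 of 10 NF-kB and cytokine genes, 8 and 7 of 28 unfolded protein response genes, 9 and 6 of 25 genes of cholesterol synthesis, 4 and 6 of 14 of fatty acid synthesis, and 10 and 9 of 26 NRF2 targets (10 and 10 adjusted over the list alone). They were 14 and 6 of 27 genes of homologous recombination and the DNA damage response (14 and 7 adjusted over the list alone), 14 and 21 of 43 MYC targets (14 and 22), 1 and 2 of 9 stem cell genes, 7 and 13 of 36 genes of autophagy and lysosomes, 8 and 1 of 17 replication-dependent histone genes (9 and 1) and 12 and 5 of 26 housekeeping genes. Where no second pair is given, the counts adjusted over the list alone were the same. With no filter on low values the list of homologous recombination and the DNA damage response was called, as higher (camera adjusted p = 0.0166). With the trend removed the balance turned in the histone, p53, interferon, unfolded protein response and NRF2 lists, none of them called. Then 2 histone genes were higher and 4 lower, the median going from 0.35 to 0.06. The counts were 4 and 8 for p53 targets and 5 and 4 for interferon-stimulated genes. They were 4 and 5 for unfolded protein response genes and 6 and 10 for NRF2 targets. The median GC content of these lists ran from 44.4% to 54.4%. For the G1/S, interferon, NF-kB, NRF2, MYC and stem cell lists, the median, the mean and camera's direction did not all have the same sign.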

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

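The tests with the GC content and length trend removed were chosen after seeing the data; the others in this part were set beforehand. BMI1 was lower and called under every setting that kept it, with log2 fold changes from -2.02 to -1.22; a filter at a mean of 5 FPKM removed it. The number of called genes stayed within 1.5 times of 6295 except at that filter (3478 of fewer genes tested; 1631 higher, 1847 lower) and with the trend removed (4064, 1952 of them higher); with medians over transcripts the latter count was 4426. Genes changed at least 2-fold numbered 663 with a pseudocount of 0.1 (540 higher, 123 lower), which widens the folds of low genes, 161 at the filter of 5 FPKM (131 and 30), 427 with libraries scaled to a total of 1000000 (136 lower), and 77 (54 and 23) or, with medians over transcripts, 95 (66 and 29) with the trend removed, against 260 as reported; where no reason is given, the cause was not tested. Called lists numbered 9 at the filter of 5 FPKM, 7 in both versions with the trend removed (6 of the 14 in the same direction in the first, and the mitochondrially encoded list, then lower), 0 with an estimated correlation and 27 with fry. Of the 24 genes with the largest changes, 14 were tested and called at the filter of 5 FPKM. The mean correlation within groups exceeded that between groups by 0.0295, and by 0.0355 with a pseudocount of 0.1, 0.0124 with no filter, 0.0404 at the filter of 5 FPKM, 0.0332 with libraries scaled to a total of 1000000, 0.0149 with the trend removed and 0.0172 in its other version. Leaving out 1 library at a time gave 5226 to 6122 called genes (2724 to 2982 higher, 2484 to 3140 lower), 247 to 297 changed at least 2-fold (210 to 230 higher, 36 to 69 lower), 13 to 15 lists, 21 to 24 of the 24 genes, BMI1 log2 fold changes from -1.58 to -1.22 and a difference of correlations from 0.0273 to 0.0316. Of 141 named genes, 11 lost their call in at least 1 of these 6 fits, and none of the 141 reversed in them. With the trend removed, named genes called before or after that took the opposite sign were RNF2 (-0.037), CBX6 (0.12), KDM2B (0.11), SCML1 (-0.29), CBX2 (0.16), BCORL1 (0.22), PCGF5 (-0.44), EPOP (0.13), CDKN2C (0.25) and MT-ND3 (-0.012). With medians over transcripts they were RNF2 (-0.11), CBX6 (0.11), SCML1 (-0.26), CBX2 (0.10), BCORL1 (0.24), PCGF5 (-0.44), EED (-0.26), EPOP (0.17), CDKN2B (0.088) and CDKN2C (0.23). Replicate numbers did not pair the libraries: the deviations of same-numbered libraries from their group means correlated at 0.00374, -0.0791 and -0.0234. With the replicate block 5658 genes were called, 258 at least 2-fold, and 12 lists, and BMI1 had a log2 fold change of -1.37; of the named genes and lists, the block ended the calls of the PRC1 and NOTCH lists, SCML1, CBX2, BCORL1, EED, EPOP and CDKN2B and changed no other. Depth is unknown, so no limit from counting can be given for low genes.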

Other observations

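The tests of matched lists for ribosomal, oxidative phosphorylation and G2/M genes, of the 5 secretory genes with the trend removed and of abundant genes were chosen only after the results were seen; those of the noncoding rows, of the wider secretory list and of other splits were written beforehand.

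Markers of bile duct cells and neighbouring cell types did not shift together. Of 19 cholangiocyte markers 7 rose, 6 fell and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.635; median GC content 55.1%). SPP1, osteopontin, rose from 6.30 ± 0.733 to 21.8 ± 1.99 FPKM (SD, n = 3 each) and TFF1 from 4.90 ± 0.491 to 10.0 ± 1.25 FPKM, beside TFF3 and FXYD2. Of 22 heat shock genes 13 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0762; median GC content 48.8%); HSP90AA1 rose from 16.2 ± 0.871 to 40.3 ± 2.06 FPKM and HSPD1 from 62.2 ± 4.55 to 112 ± 4.73 FPKM. With no filter on low values the heat shock list was called (camera adjusted p = 0.0292). Of 8 mesenchymal genes 2 rose and 4 fell, of 11 squamous epithelial markers 1 rose and 7 fell (camera adjusted p = 0.671 and 0.0762), and of 7 adipocyte markers 2 rose and 1 fell (camera adjusted p = 0.725), with the same counts adjusted over each list alone and a median GC content of 52.3%, 56.3% and 60.9%. With the trend removed 1 adipocyte marker was higher and 2 were lower. The squamous list was called without control replicate 2 (camera adjusted p = 0.038) and the histone list without Bmi1 shRNA replicate 3 (0.0403). Of 4 tested hepatocyte markers 3 rose and 1 fell, both endothelial markers fell, 1 of 2 immune cell markers fell, and no fibroblast or stellate cell marker was tested, too few for a test of those lists.

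Levels of lineage genes, chosen after their values were seen, showed KRT20 far above KRT7. In the control libraries KRT20 stood at 155 ± 4.62 FPKM (SD, n = 3) and KRT7 at 2.74 ± 0.0356 FPKM, LYZ at 1468 ± 50.9, S100P at 1374 ± 125, LGALS4 at 397 ± 4.02 and EPCAM at 164 ± 2.55 FPKM. CDX2 was at 0.0800 ± 0.0328 and VIM at 0.187 ± 0.0640 FPKM, and MUC2, the main mucin of intestinal goblet cells, averaged 0.00140 FPKM. The high KRT20, LYZ and LGALS4 beside low KRT7 raise a question about the identity of the line, which was not checked here.

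The first pattern is the trend with GC content, by which transcripts low in GC were higher in the Bmi1 shRNA libraries. The 3 control libraries deviated from the mean of each gene with Spearman's rho of 0.355 to 0.475 against GC content and the 3 Bmi1 shRNA libraries with -0.462 to -0.379. A few abundant genes taking up more of one group would move all other genes by one amount, which the difference of 0.632 between the median log2 fold changes of the groups lowest and highest in GC content argues against. A GC-dependent difference in library preparation or sequencing between the groups predicted the trend in noncoding rows too. Over lncRNA and pseudogene rows rho was -0.343 (-0.365 with medians over transcripts). It was -0.264 over the 345 lncRNA rows and -0.385 over the 341 pseudogene rows, whose reads can be shared with coding genes. Over both kinds of rows together, rho with length was -0.445. A technical difference of this kind may be the source, although the mitochondrially encoded mRNAs, low in GC, lay off the trend. An effect of the shRNA on the cells, untested, stays open because the labels give no batch apart from the group.

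The second pattern is the joint rise of ribosomal protein, oxidative phosphorylation and G2/M genes. Their median GC content was 49.1%, 47.9% and 44.3%, against 50.4% over all tested genes. Their median length was 1171, 1257 and 3037.5 nt, against 2919.5 nt. The ribosomal and oxidative phosphorylation medians lay in the 5th group by GC content, whose median log2 fold change was -0.12. By length they lay in the 2nd group, whose median was 0.15. If GC content and length alone were the cause, the medians of the lists would lie within those of random lists matched on both. The medians lay at the 100th percentile of the matched lists for oxidative phosphorylation genes, in all 4 ways of matching, and at the 99.87th for G2/M genes (99.05 at the lowest), which argues against that as the whole cause. For ribosomal proteins the percentile was 99.9, but 94.53 with medians over transcripts and the list's own members in the pool, so that a change in these genes and their GC content and length cannot be told apart there. An effect of lower BMI1 on these genes is one candidate explanation and a GC-linked technical difference that the matching misses another.

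The third pattern is the rise of genes of intestinal secretory cells, seen first in TFF3, SPINK4, ATOH1, NEUROG3 and GUCA2A (0.142 ± 0.0614 to 1.99 ± 0.371 FPKM). The median log2 fold change of these 5 genes was 2.06 before and 1.99 after removal of the GC content and length trend. The 5 genes were noticed because they rose, and group medians reached at most 0.49 by GC content and 0.34 by length. Removal of the trend could therefore hardly have undone their rise, and the values show only that the fitted trend is small beside it. A wider rise of goblet and enteroendocrine genes predicted that list members not yet looked at would be higher too: of 19 tested, 11 rose and 3 fell, with a median of 0.33 at percentile 99.91 of matched lists (99.72 at the lowest of 4 ways of matching), 95% of which lay between -0.24 and 0.16. HES6 rose from 24.3 ± 2.57 to 49.2 ± 2.31 FPKM and SCGN from 1.38 ± 0.263 to 4.17 ± 0.516 FPKM, but SPDEF (31.4 ± 2.36 and 35.0 ± 1.44 FPKM) did not pass and ST6GALNAC1 fell from 6.26 ± 0.576 to 3.77 ± 0.346 FPKM, and MUC2 was near 0 in both groups (means of 0.00140 and 0.00427 FPKM). As a hypothesis, lower BMI1 may go with a rise of part of these secretory genes; a difference between the cultures of the groups other than BMI1 was not tested.

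Of the 10 splits of the 6 libraries into groups of 3, only 1, the real one, gave as many called genes, with 6295, and the highest of the others gave 2. With so few splits a share under 0.05 cannot be reached.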
